A study of Mus musculus with 16 samples.

How the data were processed

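ChIP-seq libraries of mouse splenic B and T cells were analysed: 6 labelled Myc, 2 labelled Pol2 and 8 labelled IgG. Per the labels, the antibodies were anti-EGFP for Myc, Abcam ab5408 for Pol2 and Santa Cruz sc-2025 as IgG. The deposited files are lists of aligned reads in BED format, 1 line per read with chromosome, first and last position, read length and strand. They hold no counts per region, no normalised values and no region calls. Per the submitters' processing notes, CASAVA 1.0 and Bowtie 0.12.7 were used and the genome build was mm8, with no settings given in the sources used here. Whether positions count from 0 or from 1 is not stated, so each coordinate may be off by 1 base. Positions were taken as the files give them.

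Reads were 24 to 30 bases long in the first B4 Myc and IgG libraries, 25 in the T cell libraries and 45 in all others. Read length therefore differs between B and T cells and between the B4 replicates. Samples were grouped by their titles. The IgG library marked wt in its title was counted as B4 IgG replicate 2. The title of B4 Pol2 carries the same mark, which the titles do not explain. If it means wild type, the cells of these 2 libraries may differ in genotype from the EGFP-Myc cells. Which IgG library belongs to which ChIP library is not stated.

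From each file 1 read per 5′ end and strand was kept. This removed 5.26% of reads in B4 Myc replicate 1 and at most 0.0796% elsewhere. The strand offset of each library (90 to 175 bases) was estimated from the cross-correlation of strands, and reads were moved toward the fragment centre. Chromosomes 1 to 19 and X were analysed. Replicate libraries were checked for identity: their counts in 1 Mb windows differed by a chi-square of 12.9 to 72.6 per degree of freedom and they shared at most 0.588% of positions, so each was counted on its own.

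Enriched regions were called per ChIP library against the summed IgG libraries of the same cell state. The call used a one-sided Poisson test in 500 bp bins against the largest of the genome mean and the IgG rates of the bin, 5 kb and 10 kb, with IgG scaled by 10 kb background bins. Bins with a Benjamini-Hochberg value below 0.01 and at least 4-fold enrichment were merged with their neighbours. The same call with ChIP and control exchanged gave a number of regions for comparison. That number depends on the depth of both sides, so it is not the number of false calls expected. Simulated ChIP and control libraries were drawn as Poisson counts from the same smoothed IgG profile. In them the call recovered 86 to 98% of bins enriched 32-fold and 5.5 to 56% of bins enriched 8-fold. There were 0 to 2 false regions, and B0 Myc had the 56%. Differences in profile between real libraries were left out, and exchanging ChIP and control in B4 Myc replicate 2 gave 304 regions.

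Replicated tests used limma with voom weights on 1 kb genome windows with at least 4 reads per library on average, chosen without regard to group. The enrichment test took the 2 B4 Myc and 3 B4 IgG libraries (15833 windows, at least 20 reads in total). The contrasts for LPS and for 10058-F4 each set Myc minus IgG of 1 state against Myc minus IgG of another, over 10 B cell libraries (37268 windows, at least 40 reads in total). There, lone libraries are assumed to vary like the replicated groups. An adjusted p below 0.05 was the threshold. Simulated libraries for these tests shared a common profile and a fixed dispersion, without the differences in profile seen between real libraries. Recovery and false calls apply to that setting. In simulated data the enrichment test found 51 of 100 windows changed 4-fold and 96 of 100 changed 8-fold, with 6 false calls. The LPS contrast found 1 and 3 of 100, and the 10058-F4 contrast 0 and 5 of 100. A contrast of the same form for T4 against B4, on 7 libraries (13918 windows), was added after seeing the data and found 0 and 0 of 100. No test was run on T14, whose labels are in doubt, nor on Pol2, with 1 library on each side.

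Enrichment at regions was log2 of ChIP over IgG reads, each scaled to library size (RPM), in 1 kb around the summit, with 0.1 RPM added to both. Medians have order-statistic 95% intervals and shares have Clopper-Pearson 95% intervals. Overlaps needed 1 shared base and were set beside 100 random placements on the same chromosomes. Folds within deciles of Pol2 regions were ratios of summed reads with exact binomial 95% intervals. Pol2 was compared as RPM, without IgG. Named regions were the 5 with the highest and the 5 with the lowest change per comparison among called regions with at least 20 ChIP reads summed, and read counts given for them are those in 1 kb around the summit. Their counting error at 95% was taken from the ChIP and IgG reads in each value.

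The groups, tests, rule for named regions and a first list of alternatives were chosen before the data were examined. These alternatives covered stricter and looser calls, bin and window width, pseudocount, scaling, thinning, limma-trend, single IgG libraries, left-out replicates and restriction to the libraries with 45-base reads of B cells. Others were chosen after seeing the data: autosomes only, reads with a shared 5′ end kept, IgG left out or divided out of Pol2, different IgG libraries for call and level, Pol2 regions of 1 library alone and ranking by the 10058-F4 Pol2 library. The ranking of Pol2 regions into deciles and the limma fits with a replicate block from the titles of the B4 libraries were also added then. Gene lists fixed beforehand were not used here, since the gene list at hand is for another build than mm8 and coordinates were not converted. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and data.table (1.17.8) were used.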

Results

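Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse splenic lymphocytes to map Myc, a transcription factor, and RNA polymerase II (Pol2). The series title frames the question as whether Myc acts on expressed genes in general. Myc was precipitated with an antibody to EGFP, the fluorescent tag on Myc, and each cell state had control libraries made with a non-specific IgG. B cells were left untreated (B0) or were given 25 µg/ml of lipopolysaccharide (LPS), a bacterial B cell activator, for 4 h (B4). Some LPS-treated cells also received 10058-F4, a small molecule that disrupts the pairing of Myc with its partner Max. T cells were given 7.5 µg/ml of concanavalin A (ConA), a lectin that activates T cells, for 4 h (T4) or 14 h (T14).

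The 16 libraries comprised 6 labelled Myc, 2 labelled Pol2 and 8 labelled IgG. B4 had 2 Myc libraries, 3 IgG libraries and 1 Pol2 library. B4 with 10058-F4 had 1 Myc library, 2 IgG libraries and 1 Pol2 library. B0, T4 and T14 each had 1 Myc library and 1 IgG library, so comparisons that involve them carry no replicate check on that side. The labels do not say whether libraries of 1 group came from separate animals, so p-values measure only the spread between these libraries. Reads kept per ChIP library ranged from 2229806 in B4 Myc replicate 1 to 7605661 in B0 Myc. Reads kept per IgG library ranged from 1304116 in B4 IgG replicate 2 to 5338915 in B4 IgG replicate 3. Intervals on counts cover counting error only, and intervals on medians cover the spread between regions within a library. Regions are given by mm8 coordinates, and their genes were not assigned because no mm8 annotation was used here.

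In LPS-treated B cells, Myc was enriched over IgG at sites of which most, but not all, carried Pol2. Of 15833 windows of 1 kb tested, 547 were higher in Myc than in IgG and 0 were lower, with a median log2 enrichment of 2.81 among the 547. A called Pol2 region of B4 cells overlapped 98.0% of these 547 windows, against 60.6% of the 15286 other windows tested. Region calls in single libraries gave 2200 regions in B4 Myc replicate 1 and 308 in replicate 2, and 169 regions of replicate 2 (54.9%, 95% Clopper-Pearson interval 49.1 to 60.5%) overlapped one of replicate 1. In the other direction, only 7.68% (6.60 to 8.87%) of the regions of replicate 1 overlapped one of replicate 2. A B4 Pol2 region overlapped 67.0% (64.9 to 68.9%) of the regions of replicate 1 and 97.4% (94.9 to 98.9%) of those of replicate 2. Random placement gave means of 1.2 and 1.1%. Pol2 in B4 was called against the same IgG libraries as Myc. Pol2 with 10058-F4 was called against other IgG libraries, and its regions overlapped 71.7 and 98.4%. Random placement of the regions of replicate 2 gave a mean overlap of 0.0747% with those of replicate 1. The calls of both Myc replicates used the same IgG libraries, which can raise their overlap. With different IgG libraries for each replicate it was 41.7% (37.6 to 45.9%) of 561 regions. Exchanging ChIP and control gave 80 regions for replicate 1 and 304 for replicate 2, the latter about as many as the 308 called. The exchanged calls used 10150487 IgG reads against 2229723 Myc reads in replicate 1 and 3240911 in replicate 2. They therefore do not give the number of false calls among the regions.

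Among the regions called in both B4 Myc libraries, the highest mean enrichment lay at 4:154836001–154836500, with a log2 enrichment of 5.25 in replicate 1 and 4.12 in replicate 2. At 4:147435001–147436000 the values were 4.73 and 4.62, and at 6:86492001–86493000 they were 4.75 and 4.27. At 1:88189501–88191000 they were 4.75 and 4.18, and at 5:142619501–142620500 they were 4.49 and 3.87. The lowest of these regions, 4:120067501–120068000, had 1.48 and 1.58, and 16:44059001–44059500 had 1.69 and 1.57. At 4:128692001–128692500 the enrichment was 1.95 and 1.35, at 4:118497501–118498000 it was 1.66 and 1.74, and at 6:113042001–113042500 it was 2.20 and 1.59.

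The test of windows was limma with voom weights and Benjamini-Hochberg adjustment at 0.05, on 2 Myc and 3 IgG libraries. IgG replicate 2 is marked wt in its title, as is B4 Pol2, and may differ in genotype if wt means wild type. Without it 152 windows were higher, and with a replicate block for the 2 pairs of Myc and IgG libraries that the titles form, on the same 4 libraries, 1424 were higher and 9 lower. The count fell to 40 with limma-trend and to 89 with scaling by background windows, to 12 without Myc replicate 1, and to 13 and 3 without IgG replicates 1 and 3. With the libraries of 45-base reads alone limma called 0 windows, and of the 420 at an unadjusted p below 0.05 only 166 were higher in Myc. In the region call replicate 1 gave 674 regions against IgG replicate 2 alone and 3810 when reads sharing a 5′ end were kept.

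Myc enrichment in untreated B cells was low at the sites occupied after LPS. At the 2200 regions called in B4 Myc replicate 1, the median log2 enrichment was 0.98 in B4 replicate 2 (0.93 to 1.05) and 0.30 in B0 (0.26 to 0.35). At the 308 regions called in B4 replicate 2, it was 2.49 in B4 replicate 1 (2.35 to 2.66) and 0.45 in B0 (0.35 to 0.56). The median difference per region was 0.59 (0.51 to 0.66) for replicate 2 and 2.01 (1.84 to 2.15) for replicate 1, each at regions called in the other replicate. B0 and replicate 2 had reads of 45 bases and replicate 1 had shorter reads. X chromosome reads were 42.0% of chromosome 3 reads in B0 Myc and 66.0 and 69.8% in the B4 Myc libraries, so these libraries differ in more than LPS. B4 replicate 2 exceeded B0 at 64.1% of the regions of replicate 1, and B4 replicate 1 exceeded B0 at 93.5% of the regions of replicate 2. In B0, the deepest Myc library, 314 regions were called, against 4 with ChIP and control exchanged. Depth favoured the Myc call there, with 7604634 Myc reads against 4209788 IgG reads. Thinned to 2229723 reads, B0 Myc gave 1 region. Of the 314, 15.0% (11.2 to 19.4%) overlapped a B4 Myc region and 67.8% (62.4 to 73.0%) a B4 Pol2 region.

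The regions of largest difference held few reads and differed in IgG as well as in Myc reads. At 17:32095501–32096000 the B4 Myc libraries had 27 and 12 reads and B0 Myc, the deepest, had 2, with 6 IgG reads summed over B4 and 5 in B0. At 12:4133001–4133500 there were 17 and 2 Myc reads against 15, with 0 IgG reads in B4 and 9 in B0. At 3:88016001–88016500 there were 17 and 8 against 14, with 2 and 12 IgG reads. At 11:59625001–59625500 there were 8 and 4 against 9, with 1 and 11, and at 5:143058501–143059000 there were 9 and 6 against 7, with 0 and 3. The opposite direction was seen at 4:44632501–44633000, with 20 reads in B0 against 2 and 0 in B4. It was also seen at 12:74042501–74043000, with 20 against 0 and 2, and at 11:95502001–95502500, with 22 against 0 and 1. At 11:95167001–95167500 there were 16 reads against 4 and 0, and at 2:118090001–118090500 there were 19 against 0 and 3. In these 5 regions B4 had 4 to 15 summed IgG reads and B0 at most 1.

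At most 1 window reached the threshold for the B0 to B4 change. limma called 0 of 37268 windows at an adjusted p of 0.05, with 1053 windows at an unadjusted p below 0.05, of which 773 were higher in B4. limma-trend also called 0, with 106 of 238 such windows higher in B4, and the split was 54 of 257 with background scaling, so their direction depended on the fit. With a replicate block for the title pairs of B4, and also without it on the same libraries, 1 window was higher in B4. In simulated data this contrast recovered 3 of 100 windows changed 8-fold, so such changes were not detectable at this replication. The difference of 0.59 was 0.14 with IgG left out, 0.34 with a pseudocount of 1 RPM (reads scaled to library size) or with background scaling, and 0.27 and 0.89 with IgG replicates 2 and 3 alone. The difference of 2.01 was 1.29 with IgG left out and 1.31 with IgG replicate 2 alone.

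With 10058-F4, Myc enrichment in LPS-treated B cells was lower than without it at most called sites. At regions called in B4 replicate 1, the median log2 enrichment with 10058-F4 was 0.36 (0.33 to 0.44), against 0.98 in B4 replicate 2. At regions called in replicate 2 it was 0.65 (0.50 to 0.78), against 2.49 in replicate 1. The median difference per region was −0.64 (−0.71 to −0.58) and −1.86 (−2.01 to −1.66). The 10058-F4 library exceeded B4 replicate 2 at 33.4% of the regions of replicate 1, and B4 replicate 1 at 9.42% of the regions of replicate 2. The call gave 32 regions with 10058-F4, fewer than the 108 with ChIP and control exchanged. The exchanged call had the greater depth, with 7427483 IgG reads against 3433354 Myc reads. Whether the 32 exceeded background therefore cannot be told from it.

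At 9:65683001–65683500, 0 Myc reads were found with 10058-F4, against 15 and 12 in the B4 libraries without it. The library with 10058-F4 had 0 reads at 18:73698001–73698500 as well, against 7 and 14, and at 17:74244001–74244500, against 17 and 10. It also had 0 at 9:120782001–120782500, against 15 and 6, and at 10:39991001–39991500, against 13 and 13. In the other direction, 9:30176501–30177000 had 11 reads with 10058-F4 against 2 and 9, with 0 IgG reads with 10058-F4 and 6 in B4. At 2:155699001–155699500 there were 8 against 0 and 15, and at 2:181149001–181149500 there were 13 against 2 and 6. At 9:119786001–119786500 there were 14 against 13 and 2, and at 5:75885501–75886000 there were 16 against 1 and 4. Scaled to library size, 1 B4 Myc library had more reads than the 10058-F4 library at 2:155699001–155699500 and at 9:119786001–119786500, and the log2 difference of 2.13 at 5:75885501–75886000 lay within its counting error of 2.42.

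limma called 0 of 37268 windows for this contrast, with 1105 at an unadjusted p below 0.05, of which 472 were higher with 10058-F4. Without B4 IgG replicate 3, 1034 of 1507 such windows were higher with it, and 442 of 793 without B4 Myc replicate 1, so their direction depended on the libraries used. limma-trend called 0, with 753 at an unadjusted p below 0.05, and simulated 8-fold changes were recovered at 5 of 100 windows. The difference of −0.64 was −0.25 with IgG left out, −0.36 with a pseudocount of 1 RPM, −0.40 in 2 kb windows and −0.34 with B4 IgG replicate 2 alone. The difference of −1.86 was −1.09 with B4 IgG replicate 2 alone, and also −1.09 when the call and the level used different IgG libraries.

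**Figure D1:**
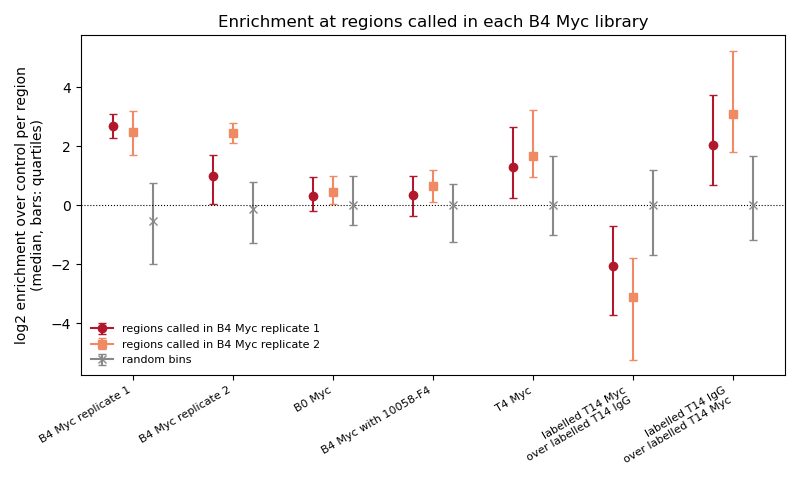
Median log2 enrichment over control (vertical axis) of each library (horizontal axis) at the regions called in B4 Myc replicate 1, at those called in replicate 2 and at 5000 random bins, with bars from the lower to the upper quartile. A library's value at its own regions is raised by the choice of regions, and the B0 and 10058-F4 medians lie between 0.30 and 0.65 while T4 has 1.31 and 1.69.

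In T cells given ConA for 4 h, many of the called Myc regions overlapped a Myc region of LPS-treated B cells. The T4 Myc library gave 808 regions, against 13 with ChIP and control exchanged. Depth favoured the Myc call here too, with 4573184 Myc reads against 1842976 IgG reads. Of these 808, 39.4% (36.0 to 42.8%) overlapped a B4 Myc region, where random placement gave a mean of 0.0693% and at most 0.371%. Of the 1678 strongest B4 Pol2 regions, chosen without regard to T4, 30.5% (28.3 to 32.7%) overlapped a B4 Myc region. At the 2339 regions called in either B4 Myc library, the median log2 enrichment in T4 was 1.31 (1.20 to 1.42), against 0.87 (0.80 to 0.89) at B4 Pol2 regions. T4 was over 2-fold at 56.1% of these B4 Myc regions, 45.9% of B4 Pol2 regions and 35.8% of random bins. A B4 Pol2 region overlapped 88.4% of the T4 Myc regions (86.0 to 90.5%).

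The largest T4 excess was at 7:102043001–102043500, with 20 reads in T4 against 0 and 3 in the B4 Myc libraries. It was followed by 2:158305001–158305500 with 17 against 3 and 0, 3:104155501–104156000 with 17 against 0 and 3, 3:103124501–103125000 with 17 against 1 and 2, and 16:10325501–10326000 with 13 against 0 and 7. T4 had 0 IgG reads in these 5 regions and B4 had 7 to 13 summed. Enrichment was lowest in T4 relative to B4 at 6:114859001–114859500, with 7 and 4 Myc reads in B4 over 0 summed IgG reads, and 9 over 8 in T4. At 17:34213501–34214000 there were 13 and 5 over 3 in B4, and 4 over 7 in T4. At 4:124568501–124569000 there were 14 and 4 over 1, and 7 over 5. At 12:81864001–81864500 there were 11 and 6 over 3, and 3 over 3, and at 14:54589501–54590000 there were 10 and 9 over 2, and 10 over 6. limma called 0 of 13918 windows for the change from B4 to T4, with 308 at an unadjusted p below 0.05, of which 45 were higher in T4. limma-trend called 0, with 174 of 213 such windows higher in T4, so their direction depended on the fit. With a replicate block for the title pairs of B4, 21 windows were lower in T4 and 0 higher, against 0 and 0 without the block on the same libraries. Simulated 8-fold changes were recovered at 0 of 100 windows without the block, so such changes were not detectable by that fit. The overlap of 39.4% rested on B4 Myc replicate 1, being 13.5% without it, and the median of 1.31 was 0.70 with a pseudocount of 1 RPM.

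At 14 h the library labelled T14 IgG, and not the library labelled T14 Myc, was enriched at Myc sites. The titles of these libraries and the names of their deposited files give opposite antibodies, so each is called here by its title label. At the 2339 B4 regions, the median log2 ratio of the library labelled T14 Myc over the library labelled T14 IgG was −2.13 (−2.25 to −2.03). The call gave 7 regions in the library labelled T14 Myc and 1678 with the labels exchanged. Of these 1678, 33.3% (31.1 to 35.6%) overlapped a B4 Myc region, 20.4% (18.5 to 22.4%) a T4 Myc region and 95.5% (94.4 to 96.4%) a B4 Pol2 region. The ratio was −1.07 with a pseudocount of 1 RPM.

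Any direction between T4 and T14 depends on which label is right. Taking the library labelled T14 IgG over the one labelled T14 Myc, the largest excess over T4 was at 4:151127001–151127500, with 37 reads against 0 and a T4 log2 enrichment of −0.87. It was followed by 2:172669501–172670000 with 25 against 0, 8:125437001–125438000 with 24 against 0, 10:80696001–80696500 with 23 against 0, and 12:4933001–4934000 with 19 against 0. T4 was higher at 13:59779501–59780000, with 19 T4 Myc reads against 2 in the library labelled T14 IgG and 4 in the one labelled T14 Myc. The T4 Myc library had 21 reads at 7:102057001–102057500, 17 at 2:158305001–158305500, 16 at 12:85108501–85109000 and 27 at 4:154735001–154735500. The library labelled T14 IgG had 2, 4, 4 and 8 reads there.

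Across Pol2 regions of LPS-treated B cells, Myc enrichment was higher where Pol2 was higher. The 27609 regions called in the B4 Pol2 library were ranked by Pol2 RPM into deciles. From the lowest to the highest decile, the fold of Myc over IgG went from 1.34 (1.29 to 1.38) to 3.15 (3.10 to 3.20) in B4 replicate 1 and from 0.969 (0.939 to 1.000) to 2.09 (2.06 to 2.12) in replicate 2. In B0 it was 1.10 in the lowest decile and 1.21 in the highest, and with 10058-F4 it was 1.05 and 1.32. In T4 it was 1.22 and 1.74, with 1.86 in the decile below the highest. The library labelled T14 IgG over the one labelled T14 Myc had 1.63 and 4.67.

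**Figure D2:**
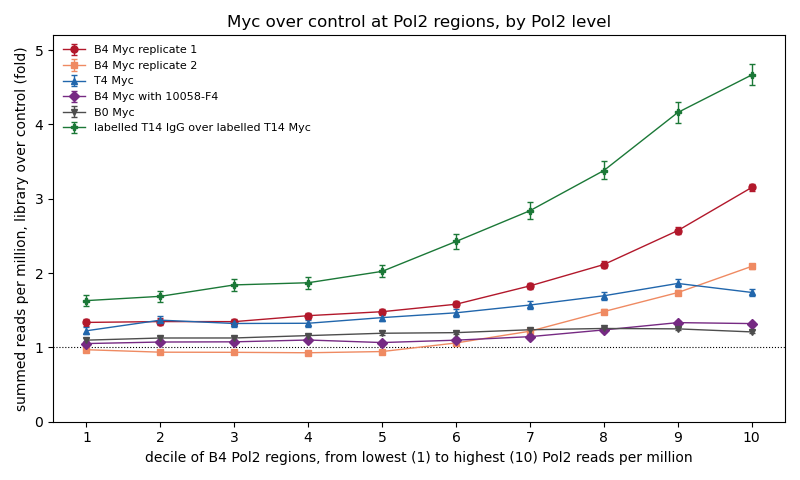
Summed RPM over control (fold, vertical axis) for 6 libraries in each decile of the B4 Pol2 regions, ordered from lowest to highest Pol2 RPM (horizontal axis), with 95% counting intervals as bars. In the highest decile the B4 Myc libraries reach 3.15 and 2.09, B0 Myc 1.21 and B4 Myc with 10058-F4 1.32.

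Ranking by the 10058-F4 Pol2 library, the highest decile had 2.87 and 1.99 in the B4 libraries. Against IgG replicate 2 alone it had 1.62 and 1.07, and that IgG library was itself higher than the other B4 IgG libraries, 1.61-fold in the lowest decile and 2.26-fold in the highest. Over 28455 windows of 1 kb with at least 24 reads over the libraries, Spearman's rho with Pol2 was 0.23 for B4 Myc replicate 1 and 0.33 for replicate 2, and −0.13 for the summed IgG. These correlations are across windows, which are not independent replicates. Between the 2 B4 Myc libraries rho was 0.24 over the same windows. The mean rho of 0.28 was 0.45 with the same IgG libraries divided out of Myc and Pol2, which can raise it. With different IgG libraries for Myc and Pol2 it was 0.21. The mean rho reversed to −0.17 over the 2994 windows with 3 times the minimum count.

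More Pol2 regions were called in the 10058-F4 library, which was the deeper, than in the library without it. The call gave 40989 regions holding 47.0% of reads with 10058-F4, and 27609 regions holding 28.1% without it. The 10058-F4 library was deeper, with 5219357 reads against 2423685, and thinning both to 2229723 reads left 28881 and 25154 regions. Of the 27609 regions, 77.2% (76.7 to 77.7%) overlapped a region called with 10058-F4. At the 2339 B4 Myc regions the median log2 change of Pol2 RPM was 0.37 (0.33 to 0.40). At the 27609 regions called without 10058-F4, Pol2 was higher with it at 15683 and lower at 11926, by over 2-fold at 3586 and 5675. At the 40989 regions called with it, Pol2 was higher at 33967 and lower at 7022, by over 2-fold at 15263 and 662, so the balance depends on which library the regions come from.

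The largest Pol2 gain was at 8:10985001–10999000, with 119 reads around the summit against 0 and 902 against 18 in the whole region. At 3:84767001–84768000 and at 6:51074001–51075000 there were 62 reads against 0 around the summit. At 2:101858001–101859000 there were 60 against 0. At 11:104461001–104464000 there were 59 against 0, and 157 against 11 in the whole region. The lowest ratio was 0.0489 (0.00552 to 0.203) at 19:10928501–10929000, with 2 reads with 10058-F4 and 19 without. At 2:119046001–119048000 it was 0.0536 (0.0104 to 0.175), with 3 reads against 26. At 10:92686501–92687500 it was 0.0633 (0.0121 to 0.211), with 3 against 22. At 4:44595001–44598000 and at 2:166729001–166731000 it was 0.0697 (0.0133 to 0.235), with 3 against 20.

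With 1 Pol2 library on each side, this comparison is between libraries and has no replicate check. The change of 0.37 was 1.00 with background scaling, 0.57 at the 47123 Pol2 regions, 0.17 at the 27609 regions of the library without 10058-F4, 0.72 at the 40989 regions of the library with it, and 0.033 (−0.020 to 0.099) with IgG divided out. With IgG divided out it turned negative against B4 IgG replicate 1 alone (−0.17) or replicate 3 alone (−0.24) and was 0.45 against replicate 2 alone. Of these IgG libraries, only replicate 2 had an X chromosome share (36.8% of chromosome 3 reads) near that of B4 Pol2 (36.9%). Replicates 1 and 3 had 66.4 and 65.9%. The 0.45 still took both 10058-F4 IgG libraries summed. Their shares were 38.7 and 60.1%, against 35.1% in Pol2 with 10058-F4. The pairing of IgG and Pol2 libraries is not stated, so the sign with IgG divided out stays open.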

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

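The tests of exchanged labels and of a loss of Myc were chosen after the result was seen, and the 2 of a control antibody that pulled down open chromatin before their results were seen. The difference between T4 and T14 was not itself tested.

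Myc enrichment at regions called in B4 cells had opposite signs at the T cell time points, with a median log2 ratio of 1.31 in T4 and −2.13 for the library labelled T14 Myc over the library labelled T14 IgG. The library labelled T14 IgG, meant as a control, also gave 1678 regions against the library labelled T14 Myc. Whether a loss of Myc from chromatin by 14 h with correct labels was the whole cause cannot be told from these 1678 regions. IgG libraries of the other states, summed per state and called against Myc or Pol2 libraries, gave at most 304. B4 IgG replicate 2, itself higher than the other B4 IgG libraries at strong Pol2 regions, was not called alone. The 304 may therefore not bound what 1 IgG library gives. An exchange of the antibody labels is consistent with the overlap of 42.5% of T4 Myc regions with a region of the library labelled T14 IgG, and with the names of the deposited files. A control antibody that pulled down open chromatin, alone or with a loss of Myc, cannot be told apart from it: 20.4% of the regions overlapped T4 Myc regions, above the 16.4% of equally many of the strongest B4 Pol2 regions, but 33.3% (31.1 to 35.6%) overlapped B4 Myc regions, where the strongest B4 Pol2 regions had 30.5% (28.3 to 32.7%).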

How the results depend on the processing

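The fits without a replicate are among the alternatives fixed beforehand; IgG left out or divided out of Pol2 with all its libraries, different IgG libraries for call and level, reads with a shared 5′ end kept and Pol2 regions of 1 library alone were chosen after seeing the data. The titles form 2 pairs of B4 Myc and IgG libraries; their deviations had a correlation of 0.0944 over the windows of the enrichment test. Paired fits with a replicate block for them, added after seeing the data and without IgG replicate 2, called 1433 windows for enrichment (1424 higher, 9 lower), 1 for the B0 to B4 change, 0 for 10058-F4 and 21 for T4 against B4 (all lower in T4). Without the block the same libraries gave 152, 1, 0 and 0. Under the alternatives, the main results kept 105 values within their interval (or 1.5 times, for counts), 91 moved further and 3 reversed; for the 60 named regions, 254 of 300 values stayed within counting error of their few ChIP and IgG reads, 46 moved and 0 reversed. Among the 105 kept values are limma contrasts between states with 0 windows called both in the main fit and in the alternative. In simulated data the contrasts for LPS, 10058-F4 and T4 recovered 3, 5 and 0 of 100 windows changed 8-fold. Agreement of 0 with 0 there is no evidence of stability. For Myc in the highest Pol2 decile, 13 values moved beyond counting error and 2 did not. With autosomes only, no main value moved beyond these bounds. Where no construction shows it, the cause was not tested. Depth limits most region calls. Thinning every ChIP library to 2229723 reads left 183 regions in T4 Myc (808 as sequenced) and 134 in B4 Myc replicate 2 (308). It left 1 in B0 Myc (314), 0 with 10058-F4 (32) and 960 in the library labelled T14 IgG (1678). The library labelled T14 Myc had 7 before and 7 after thinning, and whether these were the same regions was not compared.

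Under the stricter call (0.001 and 8-fold), which admits fewer bins by construction, regions numbered 1094 in B4 Myc replicate 1, 142 in replicate 2, 397 in T4 Myc, 1 in the library labelled T14 Myc, 5 in B0 Myc and 5 with 10058-F4. Under the looser call (0.05 and 2-fold) they numbered 4530, 491 and 1702 in the first 3 of these, 1277 in B0 Myc and 120 with 10058-F4. Bins of 1 kb gave 1377 in T4 Myc and 21 with 10058-F4. Against IgG replicate 2 alone there were 674 in B4 Myc replicate 1, 133 in replicate 2 and 17474 in B4 Pol2. Replicate 2 gave 467 against IgG replicate 1 alone and 561 against replicate 3 alone, and the 10058-F4 Myc library gave 74 against its IgG replicate 2 alone. Keeping reads with a shared 5′ end gave 3810 in B4 Myc replicate 1.

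Windows higher in B4 Myc than IgG by limma numbered 547, against 40 with limma-trend, 89 with background scaling, 51 of 278 windows at 3 times the minimum count and 3 to 479 when 1 library was left out (3 without IgG replicate 3, 12 without Myc replicate 1, 13 without IgG replicate 1, 152 without IgG replicate 2). With B cell libraries of 45-base reads alone, limma called 0, with 420 windows at an unadjusted p below 0.05 of which 166 were higher in Myc, and 1 Myc library was left. For the B0 to B4 change limma called 0 to 1 when 1 library was left out (1 without B4 IgG replicate 2), and for 10058-F4 it called 0 in every alternative run, with 6 to 2015 windows at an unadjusted p below 0.05. For the change from B4 to T4, added after seeing the data, it called 0 in each fit without a block.

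The B4 minus B0 difference at regions of replicate 1 (0.59) was 0.34 with a pseudocount of 1 RPM, 0.34 with background scaling, 0.40 in 2 kb windows, 0.77, 0.27 and 0.89 against B4 IgG replicates 1, 2 and 3 alone, and 0.14 with IgG left out. At regions of replicate 2 (2.01) it was 1.46 with 1 RPM, 2.24 in 500 bp and 1.68 in 2 kb windows, 2.38, 1.31 and 2.31 against the same IgG libraries alone, 1.41 with different IgG libraries and 1.29 with IgG left out. The 10058-F4 difference at regions of replicate 1 (−0.64) was −0.36 with 1 RPM, −0.76 in 500 bp and −0.40 in 2 kb windows, −0.86, −0.34 and −0.95 against B4 IgG replicates 1, 2 and 3 alone, −0.49 against 10058-F4 IgG replicate 2 alone, −0.49 with different IgG libraries and −0.25 with IgG left out. At regions of replicate 2 (−1.86) it was −1.39 with 1 RPM, −2.07 with background scaling, −2.13 in 500 bp and −1.53 in 2 kb windows, −2.12, −1.09 and −2.16 against B4 IgG replicates 1, 2 and 3 alone, −1.09 with different IgG libraries and −1.37 with IgG left out.

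T4 enrichment at B4 regions (1.31) was 0.70 with 1 RPM, 1.44 with background scaling, 1.67 in 500 bp and 0.95 in 2 kb windows. The 1.67 is the value that 1 T4 Myc read over 0 T4 IgG reads gives, so the pseudocount sets it. It is also the upper quartile of T4 at random bins in 1 kb windows. The T14 ratio (−2.13) was −1.07 with 1 RPM, −2.49 with 0.02 RPM, −2.44 in 500 bp and −1.78 in 2 kb windows. The T4 overlap (39.4%) was 34.8% under the stricter call and 13.5 to 36.5% without 1 B4 Myc library, with the lower value without replicate 1. The Pol2 change (0.37) was 0.29 with 1 RPM, 1.00 with background scaling, 0.57 at Pol2 regions, 0.17 and 0.72 at regions of the Pol2 library without and with 10058-F4, and 0.033 with IgG divided out, when it was −0.17, 0.45 and −0.24 against B4 IgG replicates 1, 2 and 3 alone and 0.034 and 0.18 against 10058-F4 IgG replicates 1 and 2 alone. The mean rho of Myc and Pol2 (0.28) was 0.45 with IgG divided out, 0.21 with different IgG libraries and −0.17 at 3 times the minimum count.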

Other observations

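All tests of explanations in this part were chosen after the results they concern had been seen, and the scan of 100 kb windows was too.

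T and B cell libraries differed in read depth at a few stretches of the genome. The scan set the T cell libraries against the B cell libraries other than Pol2. Of 24671 windows of 100 kb, the lowest T over B ratios of reads relative to their surroundings were at 6:41200001–41300000 (log2 −1.20) and 14:53000001–53100000 (−1.18), followed by 1:46500001–46600000 (−1.09), X:8700001–8800000 (−1.06) and 1:46300001–46400000 (−1.05). The highest was at X:52300001–52400000 (1.36), and the next 4 lay on chromosome 12 between 114200001 and 115100000 (1.03 to 1.23). Relative to flanks of 3 Mb, 6:41200001–41300000 had 0.238 to 0.433 in the 4 T cell libraries and 0.621 to 0.912 in the B cell libraries other than Pol2, but the Pol2 libraries of B cells had 0.344 and 0.275. On chromosome 12, from 114000001 to 115500000, the 4 T cell libraries had 0.389 to 0.716 of the flank depth and the B cell libraries other than Pol2 had at most 0.349. As background, T cell receptor loci lie on mouse chromosomes 6 and 14 and the immunoglobulin heavy chain locus on chromosome 12, and mm8 annotation was not used here.

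From 52700001 to 53100000 on chromosome 14, reads relative to the flanks were 0.345 to 0.630 in the 4 T cell libraries, of either antibody label. Short reads that cannot be placed there are argued against as the whole cause, since the lower of the B4 libraries with reads of 24 to 30 bases had 0.933 (0.827 to 1.05). Base composition is argued against too, since the 4 B cell libraries with at least as large a chromosome 3 share as a T cell library had a median of 1.12 and none below 0.933. Loss of DNA by rearrangement in T cells is a candidate explanation that cannot be told from others. The lowest value among B cell libraries other than Pol2, 0.829, lies above every T cell library. The scan that led to this stretch looked for such a difference and left the Pol2 libraries out. The Pol2 libraries of B cells had 0.363 and 0.310, and why was not tested.

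Pol2 regions were more numerous with 10058-F4, and Pol2 was higher with it at 82.9% of the regions called with it, but at 56.8% of those called without it and, with IgG divided out, at 51.3% of B4 Myc regions. One common yield of the precipitation, scaling all regions alike, cannot be told apart: the SD of the log2 ratio over 9885 regions with at least 100 reads, 0.589, was 2.30 times that of counting error, and no pair of Pol2 replicates shows the spread between replicates. Library size cannot be told apart as the cause of the count: the ratio of regions with to without 10058-F4 was 1.48 as sequenced and 1.15 after thinning both libraries to 2229723 reads. An effect of 10058-F4 on Pol2 may add to these, and with 1 library on each side it stays open.

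The share of X chromosome reads, as a percentage of chromosome 3 reads, differed between libraries of the same cell type. It was 65.9 to 69.8% in both B4 Myc libraries and in B4 IgG replicates 1 and 3, but 36.8% in B4 IgG replicate 2 and 36.9% in B4 Pol2. It was 62.4% in B4 Myc with 10058-F4, 60.1% in 10058-F4 IgG replicate 2, 38.7% in replicate 1 and 35.1% in Pol2 with 10058-F4. B0 Myc had 42.0% and B0 IgG 43.6%. T4 Myc had 52.2%, T4 IgG 57.5%, the library labelled T14 Myc 46.7% and the library labelled T14 IgG 40.0%.

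The widest Pol2 region of B4 cells spanned 25 kb at 13:43795001–43820000, with 1928 Pol2 reads. The next spanned 18 kb at 7:110062501–110080500, with 736 reads. At 2 to 5 kb from the summits of B4 Pol2 regions, Pol2 depth was 18.2% (17.8 to 18.6%) of the summit depth without 10058-F4 and 17.2% (16.8 to 17.5%) with it.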
